A study of Mus musculus with 8 samples.

How the data were processed

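RNA was sequenced from 8 mouse prostate samples, 4 in each of 2 groups, and each sample's group was taken from its genotype label. Both groups carried a heterozygous deletion of Pten, a phosphatase that restrains PI3K signalling and a tumour suppressor of the prostate. The groups differed in Ncoa6, a nuclear receptor coactivator that belongs to a histone H3 lysine methyltransferase complex. Deletion was driven by ARR2PBi-Cre, a Cre recombinase under a modified probasin promoter that is active in prostate epithelium. The Ncoa6 wild-type samples were labelled as prostates with PIN (prostatic intraepithelial neoplasia, a precursor lesion), and the Ncoa6 knockout samples as prostate tumours. All mice were untreated C57BL/6 animals aged 9 months. Because the genotype and the histology changed together, the comparison cannot separate them. The labels number the replicates 1 to 4 in each group and do not say that equal numbers share a litter or batch, nor that each sample came from a separate animal, so the p-values measure the spread between these samples.

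Per the labels' protocols, total RNA was extracted with TRIzol and purified on RNeasy columns, 250 ng was used with ERCC spike-in controls, poly(A) RNA was selected, and strand was marked with dUTP before 15 cycles of PCR. The submitters' processing notes name STAR, DESeq2 and the mm10 genome, with no versions and no roles. The program that counted reads, its strand setting and the annotation are not given in the sources used here. Genes that overlap or have near-identical copies, such as the Tmprss11, Sprr, Krt6 and Defb families, are therefore less certain than others.

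The 1 table used here holds 24054 genes and 5 kinds of values, each per group or per comparison. The mean raw counts per group were computed by the authors before they deposited the table. The mean RPM per group (counts scaled to a common library total) was also computed by the authors, and the deposited RPM of a gene with a mean count of 0 was 0.0191 in the wild type and 0.0186 in the knockout, so that about 1 read had been added to each count. The RPM of the listed genes summed to 79.5% and 77.6% of the total to which RPM is scaled, in the wild type and the knockout. The fold is the authors' deposited ratio of knockout over wild type, from DESeq2 per the file headers, with falls given as a negative inverse. The p-value and the false discovery rate were deposited by the authors beside the fold, and the deposited adjusted p equalled a Benjamini-Hochberg adjustment of the deposited p to within a log10 difference of 1.7e-05. No ERCC gene was listed (0 rows).

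No value per library was used, because the columns are group means. The count test planned for values per library was therefore replaced by the branch fixed for this case: the authors' deposited folds and adjusted p, at a threshold of 0.05, with no test across libraries here. Of the 24054 genes, 19898 had a fold, 19858 a p-value and 18332 an adjusted p, and those with an adjusted p are called tested. The other 4156 genes had no count in either group. Mean counts times 4 were whole numbers for every gene (largest distance 0).

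A standard error on the log2 scale was computed for each gene as the size of the deposited log2 fold divided by the normal quantile of its p-value. It assumes that the deposited p-value is a Wald test of the deposited fold, and every value after ± is this implied standard error. It reached at most 1.00, and its median was 0.0917 for genes with mean counts of 1000 or more in both groups and 0.34 at 10 to 100 counts. The deposited folds of genes with few counts were smaller than the ratios of their counts, as a shrinkage prior gives, so folds against a group with 1 to 3 counts are given with the ratio of counts and its exact 95% interval. These intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The recomputation was tested on simulated data for 18330 genes with 200 changed genes. The true standard error was recovered to within 1% in 100% of genes. This checks the arithmetic only, because the simulated p-values were Wald tests by construction, and whether the deposited ones are was not tested. Of the changed genes, 65.0% with a log2 fold of 1 and 79.0% with a log2 fold of 2 were called, and 4.00% of the calls were unchanged genes. Far fewer genes were changed in the simulation than passed the threshold in the data.

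Before the data were examined, 39 gene lists were fixed, 23 on biology, 12 on cell types and 4 on sample quality, with 907 members, of which 27 had no match in the table and 11 were matched through a synonym. They cover 854 genes, and 26 of these are in more than 1 list. Lists with at least 5 tested members (37) were tested with camera (limma 3.58.1 in R 4.3.3) on the implied z statistics against all other tested genes, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the tested lists. An estimated correlation between genes, and fry, need values per library and were not run, so the list calls rest on the preset correlation. In simulated data with independent genes, camera called 2.00%, 1.00% and 4.00% of unshifted lists of 10, 20 and 30 genes and 100% of lists shifted by 1.5 in z. These rates do not cover lists whose members are correlated. Medians of lists have 95% bootstrap intervals (10000 draws of member genes), which cover the spread among members and not between samples. The percentile of each median was taken among 10000 random lists matched on expression in 20 bins. Neither measure takes account of correlation between genes. Where members had 0 to 3 counts over a group, the median was also taken with those genes at their counting bound. This moved the median of the neutrophil list from 5.10 to 4.81, of the adipocyte list from 0.39 to 0.64 and of the skeletal muscle list from -0.26 to -0.50. It moved no other tested list's median.

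The genes named in the text were fixed by rule before the data were examined. They are Ncoa6 and Pten, the 6 largest rises and 6 largest falls among genes past the threshold with at least 5 RPM in a group, and for each list that was called or had at least 1 in 3 of its tested members past the threshold the members with the smallest p (2 for lists on biology, 1 for the others). Predicted genes, clone names and receptor segments were left out of the largest changes, and the condition that libraries of the groups must not overlap could not be applied to group means. Members of the fixed lists named beyond this rule were chosen as examples after their values were seen, as was the list of stratified squamous genes. Coordinates are from the GENCODE M21 annotation of GRCm38, the assembly also called mm10. That of Tmprss11bnl is from the RefSeq annotation of the same assembly, which lists the name as a synonym of Tmprss11b.

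Alternatives to the scaling were computed by shifting every log2 fold and recomputing the p-values from the implied standard errors. They were the ratio of the deposited mean RPM (library total scaling), totals without the 20 most abundant genes, and a trimmed mean of the log2 ratios with 30% trimmed on each side. Other alternatives were all genes with a p-value, a mean count of at least 50 in a group, a test against a fold of 1.5, an absolute log2 fold above 1, camera on ranks and camera on genes above the median expression. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.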

Results

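The transcriptomes of 8 mouse prostate samples were compared to ask which genes differ between prostates with PIN of Pten heterozygous mice (Ncoa6 wild type, 4 libraries) and prostate tumours of Pten heterozygous mice that also lacked Ncoa6 in prostate epithelium (Ncoa6 knockout, 4 libraries). The mean total count per library was 41673674 reads in the wild type and 41664848 reads in the knockout. In the wild type, 22.2% of the counts came from 1 transcript, 9530053A07Rik, against 2.69% in the knockout. Each group's own 3 most abundant genes took 28.8% in the wild type and 5.0% in the knockout. Folds, adjusted p and group means are those of the authors' deposited table throughout, knockout over wild type, and values after ± are the standard errors that the deposited fold and p-value imply. RPM is scaled to library totals and the folds are not, so a pair of RPM values does not give the fold beside it. The ratio of RPM, knockout over wild type, was a median of 1.46 times the deposited fold. List members named beyond the rule for named genes were chosen after their values were seen.

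Ncoa6 was lower in the knockout. In the authors' deposited table its mean level was 47.1 RPM in the wild type and 35.5 RPM in the knockout, a 1.94-fold fall (log2 fold -0.95 ± 0.07, adjusted p = 3.9e-39). Counts over the whole gene (chromosome 2, 155390656 to 155473894, minus strand, GRCm38) include exons that the deletion leaves in place and transcripts of cells that do not express Cre. Pten (chromosome 19, 32757497 to 32826160, plus strand) had 1 deleted allele in both groups. Its deposited means were 41.3 and 68.0 RPM, with a log2 fold of 0.17 ± 0.11 (adjusted p = 0.17). Scaling to library totals gave -0.41 for Ncoa6, still past the threshold, and 0.72 for Pten with an adjusted p of 3.9e-10, while leaving the 20 most abundant genes out of the totals gave 0.31 for Pten (adjusted p = 0.0099).

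Among 18332 tested genes in the authors' deposited table, 12009 passed an adjusted p of 0.05, with 6293 higher and 5716 lower in the knockout. The split depended on the scaling. Library totals shifted every log2 fold up by 0.55 and gave 10719 genes higher and 2243 lower, so the share of higher genes rose from 52.4% to 82.7%. Leaving the 20 most abundant genes out of the totals cut the shift to 0.14 and gave 7293 genes higher and 4624 lower (61.2% higher). Each group's own 20 most abundant genes held 35.3% of the counts in the wild type and 11.1% in the knockout. Results with library totals below therefore carry this difference in a few abundant genes. Against a fold of 1.5, 3383 genes were higher and 2015 lower. The median log2 fold of all tested genes was 0.05 as deposited and 0.60 with library totals, and changes below are relative to the deposited scaling.

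The largest rises were in genes of stratified squamous epithelium and an inflammatory chemokine. Krt6b, a keratin of stressed or stratified epithelium (chromosome 15, 101676023 to 101680287), and Crnn, which encodes the squamous protein cornulin (chromosome 3, 93144787 to 93149819), were near the floor in the wild type, with 2 counts each over the 4 libraries, and stood at 60.9 and 35.8 RPM in the knockout. Tmprss11bnl, Tmprss11g and Tmprss11d, members of a cluster of transmembrane serine proteases on chromosome 5 (86659522 to 86676298, 86485876 to 86518600 and 86302217 to 86373420), reached 85.3, 43.6 and 23.4 RPM. Ppbp, a chemokine stored in platelets (chromosome 5, 90768518 to 90770063), reached 70.1 RPM. Their log2 folds in the authors' deposited table ran from 8.94 ± 0.71 for Tmprss11d to 9.84 ± 0.68 for Tmprss11bnl, with 9.76 for Krt6b, 9.47 for Ppbp, 9.08 for Tmprss11g and 8.95 for Crnn. These fitted folds depend on the prior, because the wild type held 1 to 5 counts of each. At the deposited scaling the ratio of counts was 4308 for Krt6b (95% counting interval 1192 to 35580), 4022 for Tmprss11bnl (1376 to 19504), 3316 for Tmprss11d (595 to 131012) and 2523 for Crnn (698 to 20835).

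The largest falls were in muscle, secretory and neuronal genes. Acta1, skeletal muscle actin (chromosome 8, 123891769 to 123894751), fell 30.7-fold from 113 to 4.51 RPM (log2 fold -4.94 ± 0.42), and Tnnc2, a skeletal troponin (chromosome 2, 164777161 to 164779967), fell 22.8-fold (-4.51 ± 0.60). Pnliprp1, a secreted lipase-related protein (chromosome 19, 58728887 to 58744169), fell 26.7-fold from 277 to 10.5 RPM in the authors' deposited table (-4.74 ± 0.60). Rbfox3, a neuronal splicing factor (chromosome 11, 118489762 to 118911597), fell 25.1-fold, Pcp4l1 (chromosome 1, 171173262 to 171196268) 22.1-fold and Grin2d, a glutamate receptor subunit (chromosome 7, 45831883 to 45878378), 18.6-fold. Their deposited log2 folds were -4.65 ± 0.28, -4.47 ± 0.18 and -4.21 ± 0.23. Adjusted p of the 12 genes with the largest changes was at most 2.9e-13, the value of Tnnc2.

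**Figure D1:**
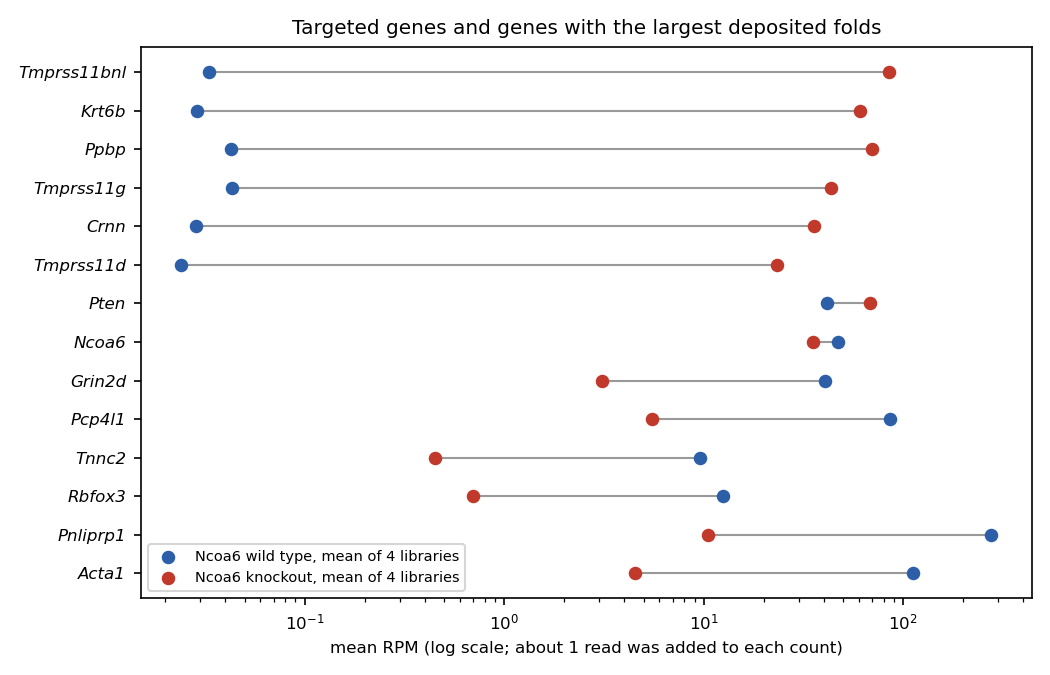
Deposited mean RPM (log axis) of Ncoa6, Pten and the genes with the 6 largest rises and 6 largest falls, for the Ncoa6 wild type (blue) and knockout (red), 4 libraries each, with no spread because the table holds group means. Tmprss11bnl went from 0.0331 to 85.3 RPM and Acta1 from 113 to 4.51 RPM.

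Genes of cell division were higher in the knockout. Of 35 G2 and M phase genes, 34 rose and none fell over all genes tested (34 adjusted over the list alone), with a median log2 fold of 2.60 (95% interval 2.40 to 2.64). In the authors' deposited table Ccnb2, a mitotic cyclin, rose 6.24-fold (2.64 ± 0.21), Kif23, a kinesin of cytokinesis, rose 5.53-fold, and the proliferation marker Mki67 rose 8.29-fold from 7.75 to 97.4 RPM. Of 40 DNA replication and S phase genes, 39 rose and 1, E2f2, fell (39 and 1 adjusted over the list alone), with a median of 1.42, and E2f2 was not past the threshold with library totals. The deposited fold was 4.59 for Mcm6, a subunit of the replicative helicase (2.20 ± 0.19), and 2.86 for Lig1, the replicative DNA ligase. Camera called both lists (adjusted p = 2.2e-12 and 5.3e-10). MYC targets, mainly ribosome biogenesis genes, went both ways, with 6 higher and 13 lower of 30 (6 and 13 adjusted over the list alone). Srm, spermidine synthase, fell 3.36-fold and Ccnd1, cyclin D1, rose 2.42-fold. Camera did not call this list (adjusted p = 0.26), and with library totals 21 members were higher and 1 lower.

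Basal and proximal luminal markers of the epithelium were higher in the knockout. Of 20 basal markers, 17 rose and 2 fell over all genes tested and adjusted over the list alone, with a median log2 fold of 2.27. The basal keratins Krt14 and Krt5 rose 16.7-fold (4.07 ± 0.18, from 22.1 to 551 RPM) and 10.3-fold in the authors' deposited table, and Col17a1, a hemidesmosomal collagen, rose 4.32-fold (2.11 ± 0.14). The 2 that fell were Dst and Lama3, and with library totals none was past the threshold as lower. Of 22 markers of proximal luminal cells and of Pten loss, 21 rose and 1, Mmp7, fell (also adjusted over the list alone), with a median of 3.86. Deposited folds were 18.5 for Cp, ceruloplasmin (4.21 ± 0.22), and 2.59 for the progenitor factor Sox9 (1.37 ± 0.08). Anxa1 rose 48.3-fold to 3403 RPM and Clu, clusterin, 6.99-fold to 11087 RPM. Mmp7 was past the threshold as lower at the deposited scaling (-0.52 ± 0.22) and was not with library totals. Camera gave adjusted p of 3.1e-09 for the basal list and 3.3e-10 for the proximal luminal list.

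Luminal identity genes, androgen receptor targets and secretory proteins were not called as groups by camera, while single members rose or fell. Among the matched random lists their medians lay at percentiles 99.65, 19.9 and 70.7, so that of the luminal identity list was high by this measure. Of 20 luminal identity genes, 11 rose and 7 fell (11 and 7 adjusted over the list alone, camera adjusted p = 0.53). In the authors' deposited table Ar, the androgen receptor, rose 2.21-fold (1.14 ± 0.12) and the surface enzyme Cd38 rose 6.29-fold, whereas Nkx3-1, a luminal homeobox tumour suppressor, fell 7.33-fold from 1087 to 207 RPM (-2.87 ± 0.28), Hoxb13 fell 2.88-fold and Spdef, a luminal transcription factor, 3.18-fold. Of 29 androgen receptor targets, 11 rose and 12 fell (11 and 12 adjusted over the list alone, camera adjusted p = 0.86). Aldh1a3, a retinaldehyde dehydrogenase, rose 31.4-fold in the deposited table (4.97 ± 0.28) and Ndrg1 6.11-fold, and Pbsn, the probasin secretory protein whose promoter drives the Cre, fell 6.29-fold (-2.65 ± 0.43). Of 18 secretory proteins, 4 rose and 7 fell (4 and 7 adjusted over the list alone, camera adjusted p = 0.45). The risers were Crisp3, Folh1, Timp4 and Oit1. Those that fell included the abundant Tgm4, the prostate transglutaminase, 7.75-fold from 40790 to 6892 RPM, Pnliprp1 and Spink8, a protease inhibitor, 10.7-fold. The list summed to 54518 RPM in the wild type and 10810 RPM in the knockout. Most of this was Tgm4 and Pbsn, with 40790 and 11772 RPM in the wild type and 6892 and 2465 RPM in the knockout. The median log2 fold of the list was 0.06. Camera with library totals called the secretory list as lower relative to other genes (adjusted p = 0.024).

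Of 21 tested neuroendocrine markers, 12 rose, none fell and 9 did not pass over all genes tested and adjusted over the list alone (median log2 fold 1.30). Sox2, a progenitor and neuroendocrine factor, rose 7.01-fold in the authors' deposited table (2.81 ± 0.26) and Cplx2, a synaptic complexin, rose 2.28-fold, and both stayed under 14 RPM (13.6 and 10.5). The general markers Chga and Syp had log2 folds of 0.01 ± 0.26 and -0.13 ± 0.24. Camera did not call the list (adjusted p = 0.071), and called it on ranks (0.021). Markers of neighbouring tissues were counted beside these. Of 13 bladder and urethra urothelium markers, 9 rose and 2 fell (9 and 2 adjusted over the list alone, median 2.16, camera adjusted p = 0.0056, and 0.062 with library totals). Gata3 and Upk1b were those that fell. The transcription factor Foxq1 rose 4.48-fold in the deposited table. Other risers were Krt13 (8.74), Grhl3 (5.10), Sprr1a (2.50) and Ppl (1.95), which are also in the list of stratified squamous genes, and the basal keratin Krt5. The call of this list is therefore not specific to urothelium. Of the uroplakins that mark urothelium, Upk1b went from 194 to 137 RPM (-1.03 ± 0.17), lower also with library totals, while Upk2 rose from 1.5 to 3.3 RPM (0.59 ± 0.22, adjusted p = 0.015) and Upk3b from 0.037 to 0.28 RPM (2.39 ± 0.87, adjusted p = 0.011). Upk1a (-0.06 ± 0.21) and Upk3a (-0.63 ± 0.58) were not past the threshold. Of 9 tested seminal vesicle markers, 2, Svs3a and Svs3b, rose and 1, Cdh4, fell 9.67-fold (2 and 1 adjusted over the list alone, median 1.19, camera adjusted p = 0.95).

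Inflammatory and myeloid genes were among the strongest rises. Of 29 tested genes of the senescence-associated secretory list, 26 rose and 2 fell (27 and 2 adjusted over the list alone), with a median log2 fold of 2.80. Il1b, interleukin 1 beta, rose 38.0-fold (5.25 ± 0.20) and Mmp13, a collagenase, 24.4-fold (4.61 ± 0.28) in the authors' deposited table, and Cdkn2a, which encodes a cell cycle inhibitor of senescent cells, rose 8.55-fold to 9.27 RPM. Cxcl12 and Fgf7 fell, Fgf7 also with library totals. Of 15 tested neutrophil markers, 11 rose and 2 fell (11 and 2 adjusted over the list alone, median 5.10), and those that fell, Mmp8 and Il1r2, were not lower with library totals. The alarmin S100a8 rose 114-fold in the deposited table, from 0.163 to 27.2 RPM. Of 22 macrophage and monocyte markers, 20 rose and 1, Mertk, fell (20 and 1 adjusted over the list alone, median 2.03). Cd14, the lipopolysaccharide coreceptor, rose 10.7-fold (3.42 ± 0.15). Camera adjusted p was 5.3e-10, 1.4e-06 and 4e-09 for these lists.

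Interferon and antigen presentation genes rose together with the leukocyte markers. Of 34 interferon-stimulated genes, 32 rose and none fell over all genes tested and adjusted over the list alone (median log2 fold 2.49, camera adjusted p = 1.3e-05). Psmb8, an immunoproteasome subunit, rose 5.50-fold in the authors' deposited table (2.46 ± 0.21), the RNA sensor Ddx58 6.10-fold and Isg15 10.5-fold. All 14 genes of class II antigen presentation rose (14 adjusted over the list alone, median 1.64, camera adjusted p = 6.8e-05), among them Cd74, the invariant chain, 3.56-fold from 115 to 603 RPM and the protease Ctss 7.22-fold. Of 17 tested T and NK cell markers, 16 rose and none fell (16 adjusted over the list alone, median 1.52), with Il2rb up 4.25-fold. Camera gave an adjusted p of 0.0035 for this list, and 0.072 with library totals. Of 13 tested B and plasma cell markers, 8 rose and 1, Derl3, fell (8 and 1 adjusted over the list alone, median 1.39, camera adjusted p = 0.19). Sdc1 of this list, which epithelium also expresses, rose 6.26-fold in the deposited table.

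The stroma divided. All 22 smooth muscle genes fell (22 adjusted over the list alone), with a median log2 fold of -2.77 (95% interval -3.24 to -2.25, camera adjusted p = 3.5e-29), and 21 fell with library totals. In the authors' deposited table Myh11, smooth muscle myosin, fell 17.4-fold from 989 to 79.5 RPM, Acta2, smooth muscle actin, fell from 853 to 122 RPM and Pgm5 fell 4.43-fold (-2.15 ± 0.08). Fibroblast markers rose, 13 of 20 with 2, Gsn and Rorb, lower (13 and 2 adjusted over the list alone, median 0.89, camera adjusted p = 0.0032). Of 30 extracellular matrix genes, 22 rose and 6 fell (22 and 6 adjusted over the list alone, median 0.86, camera adjusted p = 5.2e-04). Col3a1 rose 4.24-fold from 80.4 to 499 RPM and Col1a1 4.86-fold, both fibrillar collagens. Of 24 epithelial-mesenchymal transition genes, 15 rose and 4 (Zeb1, Twist2, S100a4 and Itga5) fell (15 and 4 adjusted over the list alone, median 0.98, camera adjusted p = 0.0026), with deposited folds of 5.15 for the membrane protease Mmp14 and 3.72 for Tgfb1. Library totals left 1 member lower in each of these 3 lists.

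Other stromal cell types showed smaller or mixed changes. Of 18 endothelial markers, 14 rose and 1, the capillary and venous sialomucin Emcn, fell 2.98-fold in the authors' deposited table (14 and 1 adjusted over the list alone, median 0.55). Camera did not call the endothelial list (adjusted p = 0.11), and called it on ranks (0.019). Of 16 tested skeletal muscle genes, 5 (Acta1, Tnnc2, Ckm, Myh2 and Actn3) fell and 3 (Tnni2, Ryr1 and Ttn) rose (4 and 3 adjusted over the list alone, camera adjusted p = 0.37). Ckm, muscle creatine kinase, fell 22.6-fold, and the list summed to 129 RPM in the wild type, of which Acta1 was 113 RPM. Camera with library totals called the skeletal muscle list as lower relative to other genes (adjusted p = 0.018). Of 19 tested nerve and Schwann cell genes, 5 rose and 5 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.95), with Mbp, myelin basic protein, up 1.68-fold, Ngfr, Mal, Ncmap and Erbb3 also higher, and Mpz, Plp1, Cdh19, Prph and Gfap lower. Cdh19 and Gfap were not past the threshold as lower with library totals. Of 14 adipocyte genes, 3 rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.68), with the lipid droplet gene Plin4 down 5.08-fold, Slc2a4 and Pnpla2 also lower, and Cidea, Cfd and Car3 higher. Pnpla2 was not past the threshold as lower with library totals.

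**Figure D2:**
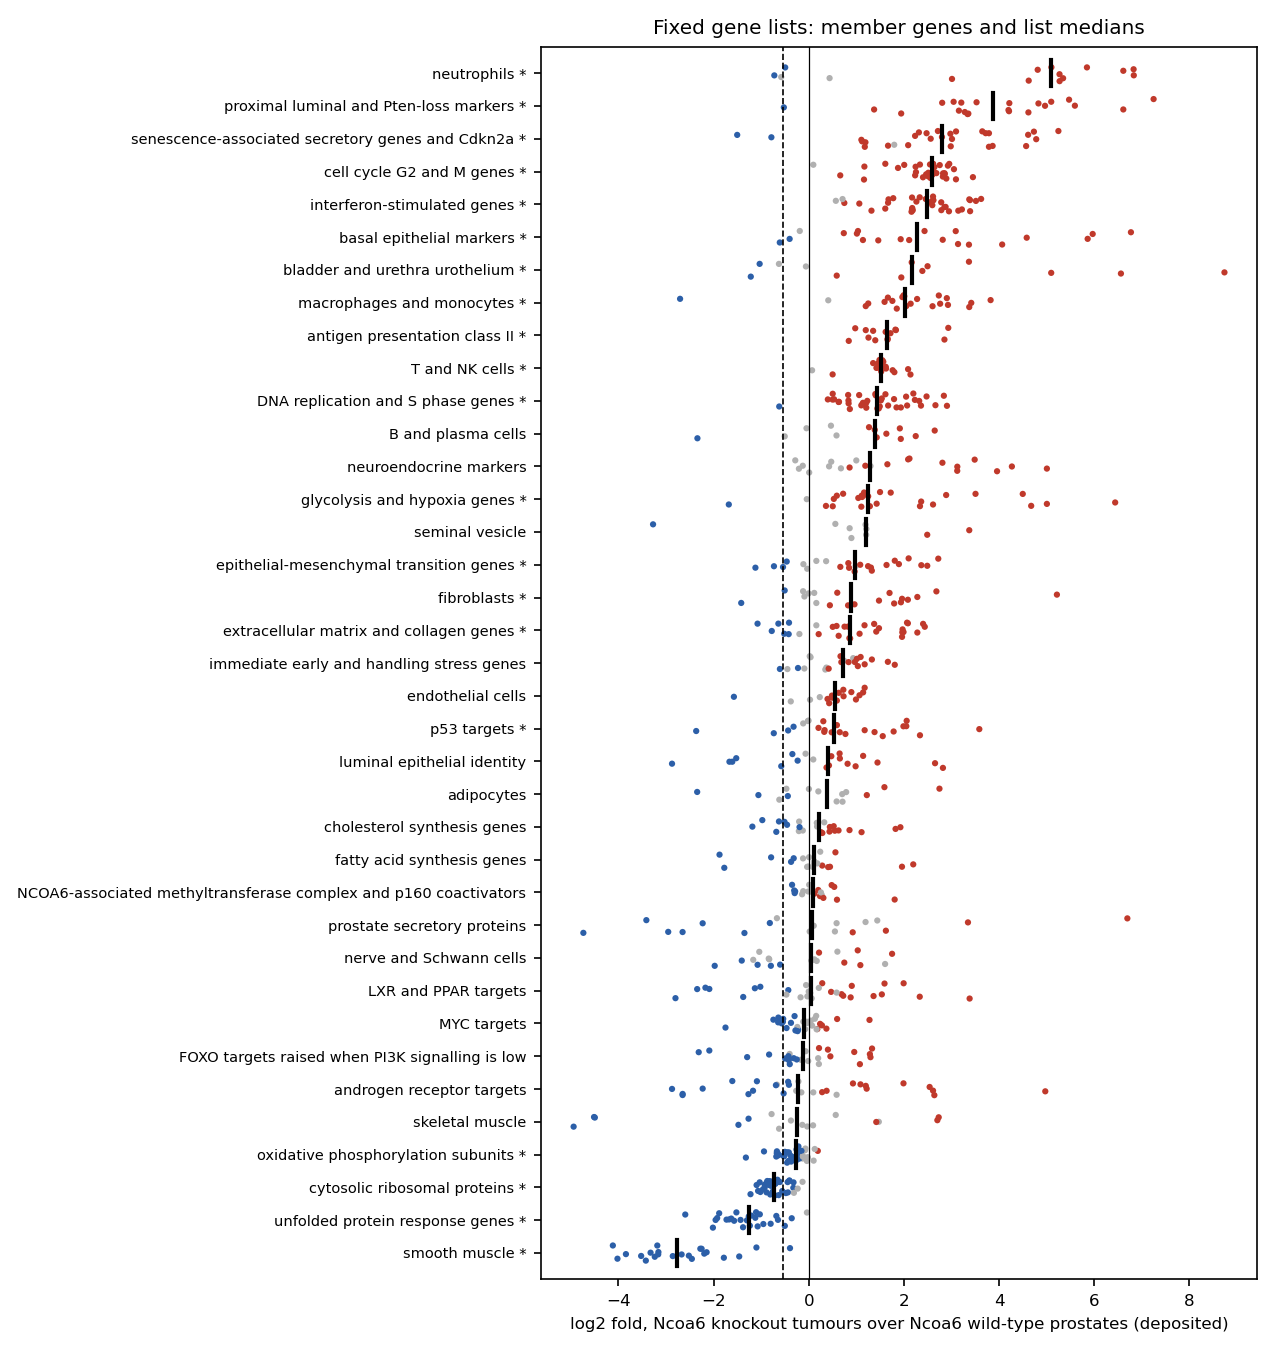
Deposited log2 folds of the tested members of each fixed list (points; red rose, blue fell, grey did not pass an adjusted p of 0.05) with list medians (black bars), and an asterisk for lists that camera called. The dashed line at -0.55 marks where no change would lie with library totals, which puts the median of the oxidative phosphorylation list (-0.27) on the other side and leaves that of smooth muscle (-2.77) on the same side.

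Glycolysis and hypoxia genes rose. Of 27 tested, 25 rose and 1, Pfkfb4, fell (25 and 1 adjusted over the list alone), with a median log2 fold of 1.25 and a camera adjusted p of 1.1e-11. Car9, a hypoxia-induced carbonic anhydrase, rose 22.6-fold in the authors' deposited table, Slc16a3, a lactate exporter, rose 25.5-fold (4.67 ± 0.30) and Hk2, hexokinase 2, rose 11.4-fold. The fall of Pfkfb4 was 3.21-fold and held with library totals. Of 24 p53 targets, 17 rose and 4 (Gdf15, Fas, Mdm2 and Rrm2b) fell (17 and 4 adjusted over the list alone, median 0.54, camera adjusted p = 0.011), of which 1 was lower with library totals. Cdkn1a, the p21 cell cycle inhibitor, rose 3.97-fold (1.99 ± 0.13) and Gdf15, a stress cytokine, fell 5.16-fold (-2.37 ± 0.13) in the deposited table.

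Genes of protein folding in the endoplasmic reticulum were lower. Of 27 unfolded protein response genes, 26 fell and none rose over all genes tested and adjusted over the list alone, with a median log2 fold of -1.26 and a camera adjusted p of 1.3e-06, and with library totals 19 fell and 1 rose. Asns, asparagine synthetase, fell 6.05-fold from 259 to 60.6 RPM in the authors' deposited table (-2.60 ± 0.24), the transcription factor Atf4 fell 2.40-fold and the chaperone Hspa5 2.46-fold. Xbp1 had -0.04 ± 0.06. Ribosomal protein genes fell, 37 of 40 with none higher (37 adjusted over the list alone, median -0.73, camera adjusted p = 1.3e-08), including Rpl10 at 2.34-fold, while library totals left 17 lower and 3 higher. Of 38 oxidative phosphorylation subunits, 27 fell and 1, Ndufs1, rose at the deposited scaling (27 and 1 adjusted over the list alone, median -0.27, camera adjusted p = 2.5e-04), but library totals turned this to 22 higher and 2 lower with the call lost (adjusted p = 0.45). The deposited median of these subunits lay only at percentile 11.2 of the matched random lists. Ndufa1 of complex I fell 2.50-fold and Sdhb of complex II 1.56-fold as deposited, and Sdhb did not pass with library totals.

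Lipid and PI3K-related lists went both ways at the deposited scaling. Of 24 cholesterol synthesis genes, 11 rose and 7 fell (11 and 7 adjusted over the list alone, camera adjusted p = 0.95). Ebp, a sterol isomerase, and Insig1, a brake on sterol synthesis, fell 1.97-fold and 2.27-fold in the authors' deposited table. Of 20 fatty acid synthesis genes, 6 rose and 5 fell (6 and 5 adjusted over the list alone, camera adjusted p = 0.93), with the acyl-CoA synthetases Acss2 and Acsl3 down 3.42-fold and 3.67-fold and Gpam, Fads1 and Scd1 also lower. Of 30 targets of the lipid-sensing receptors LXR and PPAR, 12 rose and 8 fell (12 and 8 adjusted over the list alone, camera adjusted p = 0.95). Apoe, apolipoprotein E, rose 3.98-fold and Pparg 10.4-fold, and Acox1, of peroxisomal fatty acid oxidation, fell 2.03-fold. Of 24 FOXO targets, 8 rose and 10 fell (8 and 10 adjusted over the list alone, camera adjusted p = 0.95), with Bnip3 up 2.44-fold and Tob1 down 2.45-fold. With library totals, 17, 13, 19 and 15 members of these lists were higher and 2, 3, 6 and 3 lower.

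Of 20 partners of NCOA6 in the methyltransferase complex and related coactivators, 8 rose and 4 (Ncoa1, Med1, Dpy30 and Prmt1) fell over all genes tested, and 7 and 4 adjusted over the list alone. Ncoa7 rose 3.50-fold (1.81 ± 0.21) and Ep300, a histone acetyltransferase, 1.45-fold (0.54 ± 0.09) in the authors' deposited table. Camera did not call the list (adjusted p = 0.66), while with library totals all 20 were higher and it was called (0.022). Of 22 tested immediate early and handling stress genes, 12 rose and 2, Atf3 and Jund, fell (12 and 2 adjusted over the list alone, median 0.71, camera adjusted p = 0.31), with Ier3 up 3.17-fold, and none was lower with library totals. Though camera did not call this list, its median lay at percentile 100 of the matched random lists. Of 2 tested red blood cell genes, 1, Alas2, fell (1 adjusted over the list alone) and did not pass with library totals. No mitochondrially encoded gene was in the table (0 of 13).

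**Figure D3:**
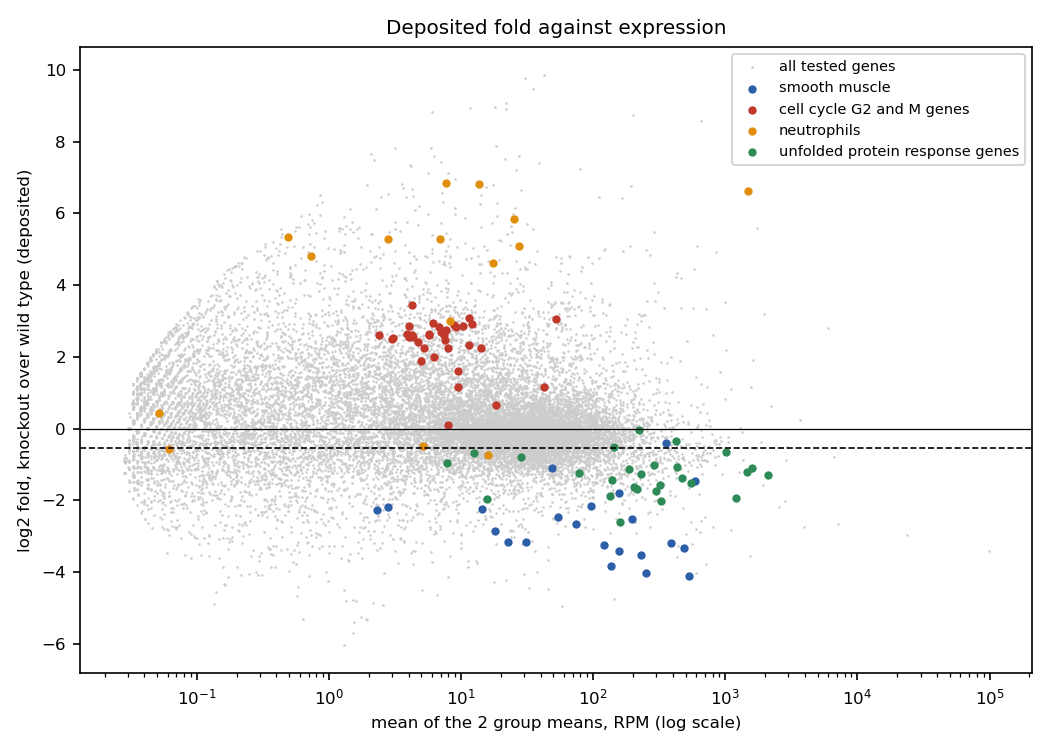
Deposited log2 fold against the mean of both groups' RPM (log axis) for the tested genes (grey) and 4 fixed lists (coloured), with a dashed line at -0.55 where no change would lie with library totals. Members of the G2 and M list centre on a median of 2.60, neutrophil markers on 5.10, smooth muscle genes on -2.77 and unfolded protein response genes on -1.26, of which 1 rose with library totals.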

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

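The tests of scaling for the squamous and smooth muscle genes, and both tests on the abundant secretory genes, were chosen after the result was seen, as were the list of squamous genes, the spread used for the epidermis ratio and the selections of secretory genes on the knockout level and on the mean of both groups. The scaling test of the squamous genes was tried in 3 forms: the lowest median over the scalings, the distance of the list from all tested genes given below, and that distance for the 9 squamous genes also in lists fixed in advance (4.53, 2.45 to 6.72). Each uses genes picked through a list written after the rises were seen. Intervals of medians in this section were drawn over member genes and do not cover the spread between samples.

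In the authors' deposited table, 40 genes had a fold but no p-value, so they entered none of the counts above. Of these, 36 were higher and 4 lower in the knockout, 19 had a mean count of 100 or more in a group, and 3 belong to the squamous list. Those with at least 5 RPM in the knockout and at least a doubling were Lypd8 at 102 RPM, Sftpd at 74.2 RPM, BC100530 at 58.9 RPM, Serpine1 at 25.8 RPM, Fmo3 at 20.6 RPM, Sprr3 at 16.2 RPM, Cnfn at 9.05 RPM and Iapp at 7.59 RPM. Lypd8 was at 5.94 RPM in the wild type, Serpine1 at 5.15 RPM and Fmo3 at 3.68 RPM, and the others were below 1 RPM. No source used here says why these genes lack a p-value, and group means do not show whether 1 library carries a level. For these 8 genes the deposited folds lay below the RPM ratios at the deposited scaling, as for Sftpd (31.2 against 201) and Lypd8 (5.32 against 11.8), and no group difference was tested for the 40 genes.

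The rise of stratified squamous genes was weighed first. Urothelium in the tumour samples was predicted to raise the uroplakins with them. Their median log2 fold was -0.060 (95% interval -1.03 to 2.39, 5 genes), below the bound of 3 set in advance. The ends of that interval are the values of Upk1b and Upk3b. Upk1b was already at 194 RPM in the wild type and fell (-1.03 ± 0.17), while Upk2 (0.59 ± 0.22) and Upk3b (2.39 ± 0.87) rose. Added urothelium need not reach that bound, so the test leaves urothelium open. The squamous median lay 2.85 (2.05 to 4.54) above that of all tested genes, which restates the rise by which the list was chosen. A scaling moves every gene alike, and each alternative scaling shifted log2 folds up, by at most 0.55. Under library totals the squamous median was 3.44, with 31 of 32 genes higher and none lower. The rise therefore did not rest on the choice among the scalings computed. Upward shifts could not have removed it, so they do not decide on scaling for these 32 genes. For skin epidermis, the log2 ratio of the mean RPM of Krt1, Krt10 and Lor to that of Krt13 in the knockout (74.0, 219, 1.42 and 397 RPM) was -2.02, under the bound of -1 set in advance, and its spread of -3.59 to -0.44 lay below the 0 or more that epidermis needs but reached past -1. That spread comes from standard errors of folds, not of levels within the knockout, so epidermis stays open, as does squamous differentiation within the tumours, which was not tested.

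The fall of smooth muscle genes was weighed next. At unchanged expression per cell, a smaller share of all stromal cells would lower fibroblast markers as much as smooth muscle genes. The smooth muscle median was -2.77 and the fibroblast median was 0.89 (95% interval 0.14 to 1.87). Expression per cell was not measured, so these values count against a smaller share only under that condition. The smooth muscle fall exceeded the scaling, with a median of -2.22 (-2.69 to -1.71) under library totals. A loss of the muscle layer around the glands in tumours, or a different part of the gland being sampled, could each produce it, and neither was tested.

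A fall of the secretory proteins as a list had been predicted and did not hold, so its tests decide nothing: the luminal identity median was 0.40 (95% interval -0.29 to 0.73) against 0.06 for the secretory list, and 0.61 (-1.24 to 1.60) for the secretory list under library totals. The 6 secretory genes above 100 RPM in the wild type, with Defb50 at 0.10 ± 0.31 among them, had a median of -2.44 (-3.85 to -0.62), and a selection on the mean of both groups gave the same 6 genes. Under library totals their median was -1.89 (-3.30 to -0.08). Both values depended on the selection. The 8 secretory genes above 100 RPM in the knockout had a median of -0.62 (-2.65 to 0.92), an interval that includes the luminal identity median. Under library totals the median of these 8 was -0.08 (-2.11 to 1.47). This cut dropped Pnliprp1, at 10.5 RPM in the knockout, and added Oit1, Sbp and Spink5. A cut on the level in 1 group favours genes higher in that group, so neither median decides alone. Fewer luminal cells therefore stay open for the abundant genes. The largest shift of the scalings computed was 0.55. Deposited log2 folds lay further below 0 than this for Tgm4 (-2.95 ± 0.42), Pbsn (-2.65 ± 0.43), Azgp1 (-2.23 ± 0.33), Rnase1 (-1.35 ± 0.26) and Pnliprp1 (-4.74 ± 0.60). The scalings computed thus did not account for the folds of these named genes. They were picked on their wild-type level and Defb50 did not fall, so scaling stays undecided for the secretory genes as a set.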

How the results depend on the processing

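The library total and trimmed mean scalings, the mean count minimum of 50, camera on ranks and the re-centred RPM ratios were chosen after the data were seen. No paired analysis was possible because the columns are group means that carry no replicate numbers. For the same reason leaving out libraries, other splits of the samples, other count models, other pseudocounts, quality weights, quantile normalisation, an estimated correlation and fry were not run, and spike-in scaling was not run with 0 ERCC rows, so no result was checked for dependence on 1 library.

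The count of 12009 genes stayed between 10744 and 12962 under the scalings and filters on low counts. It was 5398 against a fold of 1.5 (3383 higher, 2015 lower) and 5596 with an absolute log2 fold above 1 (3712 higher, 1884 lower), as stricter thresholds give by construction. Library totals moved the genes higher to 10719 and lower to 2243, through the shift of 0.55 applied to every gene. Ncoa6 at -0.95 missed the absolute log2 fold of 1 and kept its direction and call under the other alternatives. No list, and none of the 71 genes named by rule, was called in opposite directions. Other list members were, such as the 4 of the NCOA6 complex list that fell as deposited and were higher with library totals.

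Of the 20 lists called, 17 kept their call and direction under library totals. Urothelium (adjusted p = 0.062), T and NK cells (0.072) and oxidative phosphorylation (0.45) lost it, the last with its median at 0.27 in place of -0.27, and of the 17 lists not called the NCOA6 complex (0.022), secretory proteins (0.024) and skeletal muscle (0.018) gained one. All 20 calls were kept with the other 2 scalings and on ranks, where endothelial (0.019) and neuroendocrine (0.021) lists gained one. Among genes above the median expression 30 lists could be tested, and the 19 of these with a call kept it. Of 71 named genes, Sdhb lost its call with library totals (-0.10) and against a fold of 1.5, Ep300 against a fold of 1.5, and Sdhb, Ep300, Ebp and Mbp fell short of an absolute log2 fold of 1. Re-centred RPM ratios gave 10.79 for Tmprss11bnl, 10.50 for Krt6b, 10.13 for Ppbp and 9.74 for Crnn, which rest on 2 to 5 wild-type counts. Depth limits these folds, and the implied standard error was 0.34 at 10 to 100 counts against 0.0917 at 1000 or more.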

Other observations

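The gene groups and genes described here were chosen after their values were seen. Of 32 tested genes of stratified squamous epithelium, 31 rose and none fell (31 adjusted over the list alone), with a median log2 fold of 2.90 (95% interval 2.10 to 4.59), and 9 of its 35 genes are also in a fixed list. In the authors' deposited table Krt13, a keratin of wet stratified epithelia, went from 0.32 to 397 RPM (8.74 ± 0.62), Krt6a, a keratin of activated keratinocytes, from 1.65 to 382 RPM (6.77 ± 0.54) and Krt10, a keratin of differentiated epidermis, from 1.26 to 219 RPM (6.44 ± 0.51). The cornified envelope precursor Ivl rose 24.1-fold, and the desmosomal genes Dsp and Jup rose 2.02-fold and 2.05-fold. Camera gave an unadjusted p of 1.2e-15, which is no independent evidence, since the list was written after the largest rises were known.

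Several genes outside the fixed lists changed at high levels in the authors' deposited table. Dmbt1, a mucosal scavenger receptor, went from 0.79 to 1297 RPM (8.58 ± 0.71), Olfm4, a secreted marker of epithelial progenitors, from 22.2 to 1127 RPM (4.44 ± 0.68) and Arg1, arginase 1, from 4.86 to 375 RPM (5.08 ± 0.65). The metallothioneins Mt1 and Mt2 fell from 1334 to 276 RPM (-2.74 ± 0.32) and from 1000.4 to 199 RPM (-2.79 ± 0.31), and fell with library totals. Bhlha15, a transcription factor of secretory cells, fell from 166 to 34.2 RPM (-2.79 ± 0.19).

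The spread that the deposited p-values imply was larger than in random lists matched on expression for most fixed lists. The median implied standard error was above the 95th percentile of the matched lists in 24 of 37 fixed lists and below the 5th percentile in 1, oxidative phosphorylation subunits (0.0814 against 0.0938). Among the 24 were interferon-stimulated genes (0.489 against 0.0997), androgen receptor targets (0.183 against 0.107) and smooth muscle genes (0.176 against 0.105), so the gap differed between lists. The match was on the mean RPM of both groups, so it does not allow for low counts in 1 group or for the size of the change. Which libraries carry this spread cannot be read from group means.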
